A study of Mus musculus with 4 samples.

How the data were processed

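Chromatin of embryonic day 13 forebrain progenitors was crosslinked with 1% formaldehyde, sonicated and immunoprecipitated with an H3K36me3 antibody, per the labels' protocols. Reads were aligned to mm10 with Bowtie2 2.2.9, and FastQC and bedtools were also used, per the submitters' processing notes. The alignment files named in the peak lists carry the words for removed duplicates and unique alignments, per the file headers. Peaks were called with MACS, whose version is 2.1.1.20160309 per the file headers and 2.1.0 per the submitters' processing notes. Each ChIP library was called against an input in single-end mode as narrow peaks, with a p cutoff of 1.00e-05, a tag size of 150 bp and an effective genome size of 1.87e+09 bp, per the file headers. The input of the cKO library carries 2 numbers in its name, and whether inputs were pooled is not given in the sources used here. The modelled fragment length was 152 bp in WT and 185 bp in cKO, per the file headers.

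Each deposited peak list gave positions in bp, the pileup signal at the summit (the number of extended tags there), the fold enrichment over the local input background, and the -log10 of the p-value and q-value, all as the authors' run of MACS made them. The file headers state that q was not calculated, but the deposited column holds positive -log10 q-values, which served only to rank and filter peaks within a list. A score, signal or fold of 1 list was not compared with that of the other, since both depend on the tags and input of that library. A second deposited table per genotype annotated each peak of the list to a class and a gene with Ensembl identifiers, and the tool that made it is not given in the sources used here. Its starts were 1 bp higher than those of the peak lists, whose positions are used.

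Gene spans came from the RefSeq protein-coding genes of assembly GRCm38.p6, which has the chromosomes of mm10. The spans were chosen by chromosome name and not screened further. Some, such as that of Hbb-b1 (chromosome 7, 38285 to 39684), may not be positions on the mm10 chromosomes. Such a gene would count as unmarked, and the number of these genes was not determined. The gene names of the authors' annotation were found in it for 81.5% of WT and 81.3% of cKO genic peaks, and 84.3% and 84.6% of those peaks lay within 1 kb of the named gene. A gene was marked when at least 1 peak overlapped its body. Coverage was the share of the body inside merged peaks. A gene of at least 5 kb was called higher or lower when coverage differed by at least 10 percentage points. Coverage grows with the number of tags and with enrichment, since narrow calling of a broad mark joins fragments of a domain as signal rises. It cannot exceed the whole body, so a gene already covered in WT has less room to gain. The reference used holds no strand, so position along a gene came from the intron numbers of the authors' annotation.

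Genotypes were taken from the sample labels. The ChIP libraries held 31984670 (WT) and 32927164 (cKO) tags and the inputs 38500353 and 35026817, so both genotypes were sequenced to a similar depth. With 1 ChIP library per genotype no test between genotypes was made. Overlap of peak sets needed at least 1 bp and was set beside 100 circular shifts of the other list along each chromosome. Shares carry exact Clopper-Pearson intervals at 95%. Before the data were examined, 18 gene lists with 383 entries were fixed from general knowledge, all of which matched the reference, and some genes stand in more than 1 list. For each list the median difference in coverage was placed among 10000 random lists of the same size matched on the mean coverage of both libraries in 10 bins and on gene length in 5 bins. Local background at a peak was recovered from the authors' pileup and fold, as (pileup + 1) divided by the fold, less 1, and set against the genome background (fragment length times tags over genome size). The list percentile describes 2 libraries and is not a p-value, and it says nothing for lists whose median was 0 in both. The mean coverage holds the cKO coverage that also enters the difference, so matching on it narrows the range of the random lists. A list inside that range is therefore not shown to behave like other genes.

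The genes named were, by a rule fixed before the data were examined, the deleted gene and the Nkx2 family, 2 to 4 members per list with the largest absolute difference plus members going against the list, the 10 largest rises and 10 largest falls in coverage, the 5 peaks with the largest -log10 q per list, and the 10 strongest peaks per list without a partner. The last were summarised, as were predicted genes. Setd2 and the gene families of the closing section were chosen after their values were seen. Alternatives fixed beforehand were a -log10 q of at least 5, a fold enrichment of at least 4, the longer list reduced to the number of peaks or to the covered length of the other, peaks within 3 kb joined into domains, other overlap rules, other rules for marked genes and coverage, autosomes alone and unmatched random lists. Reduction to the covered length of the other list kept all WT peaks and only the strongest cKO peaks. A gene left without a cKO peak then had a difference equal to its WT coverage with a minus sign. The use of the authors' gene names was added after seeing the data.

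Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. They were tested with simulated differences and with random lists of real genes. For the comparison of cKO with WT coverage over 16853 genes, known differences were added to the WT peaks without noise. Differences of 15, 30 and 45 points were called in 50 of 50 genes each and one of 5 points in 0 of 50. This checks the calculation and does not measure the power or false calls of the comparison. Of 100 random lists of 30 genes marked in either library, 7 fell outside the central 95%. A check of GC content needs the genome sequence, which was not used here. The input libraries entered only through the peak calling, and their own profiles were not analysed here. The values of some single genes are not reported here.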

Results

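Trimethylation of lysine 36 on histone H3 (H3K36me3) was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in neural progenitor cells of the mouse forebrain at embryonic day 13. The mark is laid down by SETD2 travelling with elongating RNA polymerase II, and it lies over the bodies of transcribed genes. Forebrains of C57BL/6 wild-type (WT) embryos were compared with forebrains carrying a brain-specific deletion of H2A.z1 (cKO). H2A.z1 is the product of H2afz, named H2az1 in the current gene annotation, and it is a histone variant that replaces H2A in nucleosomes near promoters and enhancers. The series title places the deletion in a study of cortical neurogenesis. The 4 libraries were 1 ChIP and 1 input library per genotype. The WT ChIP library held 31984670 tags against 38500353 input tags, and the cKO ChIP library held 32927164 tags against 35026817 input tags. With 1 ChIP library per genotype there was no replicate, so every difference below is between 2 libraries, no test between genotypes was possible and no p-value is given. Intervals are exact binomial (Clopper-Pearson) intervals at 95% and cover counting error only. Coordinates are on mm10.

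The first question was how much of the genome carried H3K36me3 peaks in each genotype. The cKO library had 95750 peaks and the WT library 36820, a ratio of 2.6. The cKO peaks were also broader, with a median width of 436 bp (quartiles 275 and 798 bp) against 271 bp (quartiles 195 and 410 bp) in WT. Peaks over 2 kb made up 5.99% of the cKO list (5738 peaks) and 0.475% of the WT list (175 peaks), and the longest peak measured 22024 bp in cKO and 7758 bp in WT. Together the peaks covered 69.1 Mb in cKO and 13.3 Mb in WT, a ratio of 5.18, while the ChIP tags differed by a ratio of 1.03. On the X chromosome the difference was larger, with 1146 cKO peaks (1.197% of the list) against 138 WT peaks (0.375%), a ratio of 8.30, beside 2.58 on the autosomes. After neighbouring peaks within 3 kb were joined into domains, 18617 domains remained in cKO and 13659 in WT, a ratio of 1.36.

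Almost every WT peak lay where cKO chromatin also had a peak. Of the 36820 WT peaks, 35359 (96.0%, interval 95.8 to 96.2%) were overlapped by at least 1 bp of a cKO peak, against 3.53 to 5.02% when the cKO peaks were shifted at random along each chromosome 100 times. In the other direction, 24246 of the 95750 cKO peaks (25.3%, interval 25.05 to 25.6%) were overlapped by a WT peak, against 1.17 to 1.65% after shifting the WT peaks. Counted in bases, 95.3% of the WT peak sequence (12.7 Mb) lay inside cKO peaks, and 18.4% of the cKO peak sequence lay inside WT peaks. A single cKO peak often spanned several WT peaks. This was the case for 6080 cKO peaks that held 2 or more WT peaks, with up to 20 WT peaks inside 1 cKO peak. The cKO peaks shared with WT had a median width of 1011 bp and those without a WT partner 356 bp. The 1461 WT peaks without a cKO partner had a median width of 201 bp. The shares depended on the lists compared. When the cKO list was reduced from its strongest peaks down to the WT covered length, 30.7% of WT peaks and 92.6% of cKO peaks were shared, and a reciprocal overlap of 50% left 15.5% of WT and 5.95% of cKO peaks.

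Peaks of both genotypes lay mainly inside genes, and the additional cKO peaks were mostly intronic. Introns held 62.1% of cKO peaks (interval 61.8 to 62.4%) and 49.7% of WT peaks (49.2 to 50.2%), by the annotation class the authors gave each peak. Exons held 15.7% of cKO and 22.8% of WT peaks, transcription termination sites (TTS) 13.9% and 17.5%, and promoters 5.43% and 7.84%. Intergenic peaks made up 2.96% of cKO peaks (2.85 to 3.06%) and 2.21% of WT peaks (2.06 to 2.37%). Among WT peaks, the intergenic share was 12.9% in those without a cKO partner and 1.77% in those with one. The introns of transcripts with 10 or more introns were split into 5 equal bins from the 5' to the 3' end. There the WT intron peaks leaned toward the 3' end, from 15.5% in bin 1 to 22.4% in bin 5. The cKO intron peaks were spread more evenly, with 18.9% in bin 1 and 20.02% in bin 5. First introns held 2.44% of the cKO and 1.58% of the WT intron peaks of these transcripts. The shares of the classes depended on the lists compared, and the position within the introns was computed for the full lists alone. With the cKO list reduced to the WT covered length, 48.9% of its peaks were intronic and 1.30% intergenic, both below WT, while 9.04% lay at promoters and 19.6% at TTS, both above WT. With the list reduced to the WT number of peaks, 1.99% were intergenic, also below WT.

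**Figure D1:**
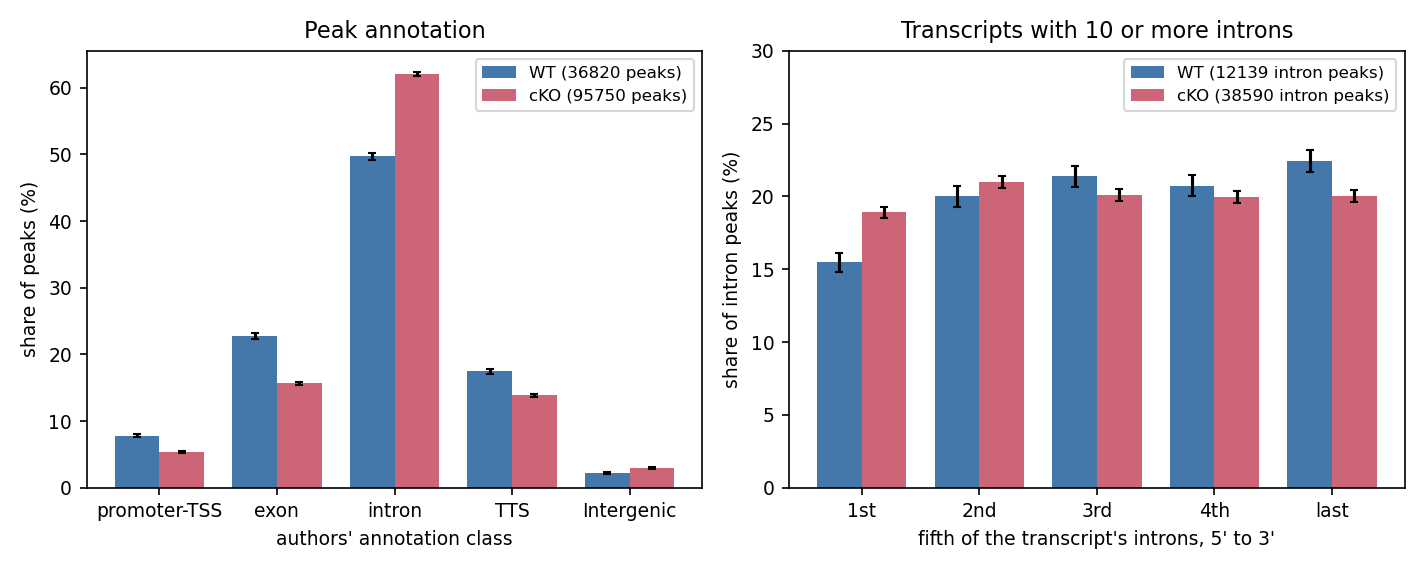
Left, share of H3K36me3 peaks (percent) in each of the authors' annotation classes, for the 36820 WT peaks (blue) and 95750 cKO peaks (red). Right, share of intron peaks (percent) in 5 equal bins of the transcript's introns from the 5' to the 3' end, in transcripts with 10 or more introns (12139 WT and 38590 cKO peaks); error bars are exact 95% binomial intervals, and the WT share was 15.5% in bin 1 and 22.4% in bin 5 while the cKO shares lay between 18.9 and 21.0%.

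The genes marked in WT were nearly all marked in cKO as well. Of 21887 protein-coding genes, 6755 had a peak over the gene body in both genotypes, 2813 in cKO alone, 106 in WT alone and 12213 in neither. Thus 98.5% of the 6861 genes marked in WT were also marked in cKO. The count in neither includes genes such as Hbb-b1, whose listed position may not be one on the mm10 chromosomes. The peaks of a marked gene covered more of it in cKO. Among the 6400 WT-marked genes of at least 5 kb, the median share of the body covered by peaks was 3.96% in WT and 29.0% in cKO, and the median difference was 22.9 percentage points (quartiles 10.1 and 37.1). Over 50% of the body was covered in 33 genes in WT and in 1555 genes in cKO. By the fixed rule of a difference of at least 10 points, 5491 of the 16853 genes of at least 5 kb had higher coverage in cKO and 0 had lower coverage. Only a gene with at least 10% coverage in WT could be called lower. Among genes of any length, 1909 had at least 10% coverage in both genotypes and 5 in WT alone. Most of the 16853 genes thus could not be called lower, which limits what the count of 0 shows. Of the 16853 genes, any difference at all was upward in 8736 genes and downward in 136. The Spearman rho of coverage was 0.857 across the 16853 genes, which are not independent replicates. Of these, 7980 had no peak in either genotype and were tied at 0. The rho thus reflects in part marked against unmarked genes and does not give the order among marked genes alone. With the cKO list reduced to the WT number of peaks, 3730 genes were higher and 5 lower. Reduced to the WT covered length, which by construction equalises the total covered bases and so removes any overall gain, it gave 810 genes higher and 373 lower. Of the called genes, 68.5% were then higher, against 100% with the full lists.

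The 10 genes with the largest rise reached 72.2 to 88.0% coverage in cKO. Clptm1l on chromosome 13 (73604002 to 73620639), which encodes a membrane protein, had 3.91% of its body covered in WT and 80.6% in cKO. Pla2g4b, a cytosolic phospholipase A2, went from 5.44 to 81.8%, and Fam83e from 12.1 to 88.0%. Mamdc4 on chromosome 2 (25563115 to 25571316) had no WT peak and 72.2% coverage in cKO. The others included genes of general RNA and protein metabolism. Snapc4, a subunit of the complex that activates small nuclear RNA genes, went from 1.75 to 72.8%, and Eif2b1, a subunit of the exchange factor of translation initiation, from 7.23 to 75.3%. The nucleolar protein gene Nol6 went from 5.24 to 73.3%, and the RNA-binding protein gene Rbm38 from 3.04 to 73.2%. Ogfr, the opioid growth factor receptor, went from 6.61 to 75.3%, and Pomgnt1, which extends O-mannose glycans on dystroglycan, from 10.3 to 78.6%. With the cKO list reduced to the WT covered length, the differences of Clptm1l, Pla2g4b and Ogfr turned to -3.91, -5.44 and -6.61 points, and that of Mamdc4 was 0. These genes then held no cKO peak, so the negative values are their WT coverage with a minus sign.

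Among genes of at least 5 kb, the 10 largest falls were all under 10 points. Tmem205 on chromosome 9 (21921009 to 21927535) had 12.8% coverage in WT and 4.32% in cKO. Asmt, which encodes the last enzyme of melatonin synthesis, had 8.28% in WT and no cKO peak. Sprr2a2 and Sprr2a1, near-identical genes of the epidermal cornified envelope, had 7.22% and 3.65% in WT and no cKO peak, and reads shared between such copies make their values uncertain. Tatdn3 (6.46%), the predicted gene Gm43707 (4.13%), Zfp992 (3.18%) and Itgad (2.81%) also had WT coverage and no cKO peak. Hjurp, the chaperone that deposits the centromeric histone CENP-A, was covered over most of its body in both, with 79.7% in WT and 75.7% in cKO (-15.8 points at matched covered length). Map6, which encodes a microtubule-stabilising protein of neurons, had 4.63% in WT and 1.51% in cKO. Of the shorter genes, which the rule leaves out, 3 had coverage lower by at least 10 points. They included Rpl34-ps1 (43.3% and 0), named after its values were seen, and Gadd45g (28.9% and 0), described with its list.

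**Figure D2:**
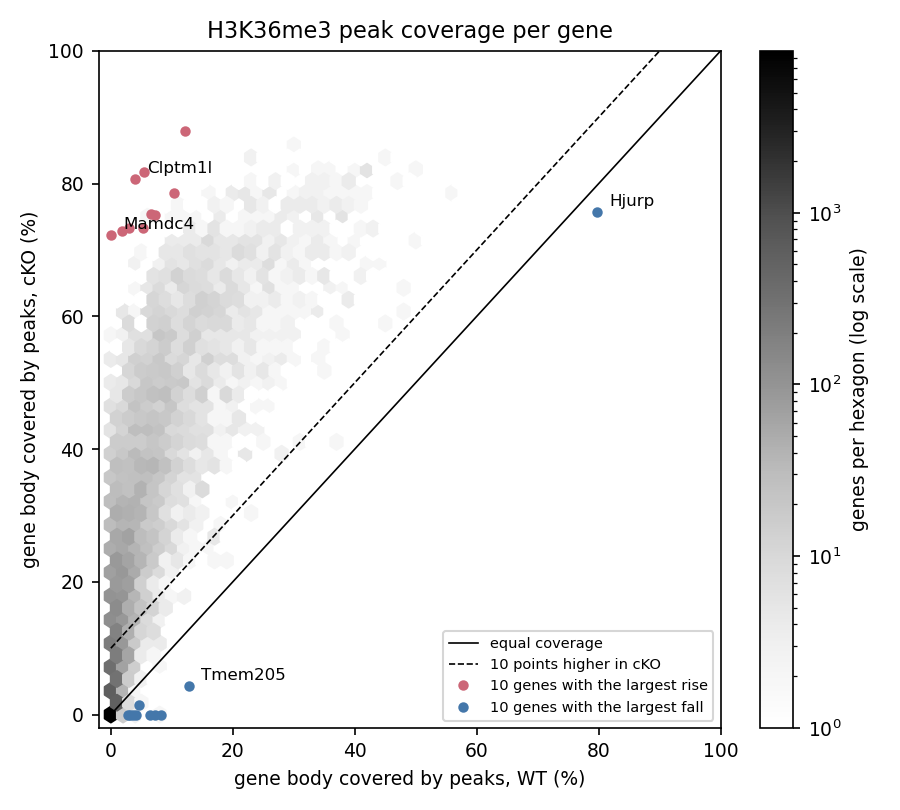
Share of each gene body covered by peaks (percent) in WT (horizontal axis) and cKO (vertical axis) for the 16853 protein-coding genes of at least 5 kb; hexagons are shaded by the number of genes on a log scale. The solid line marks equal coverage and the dashed line 10 points more in cKO, with 5491 genes on or above it; red and blue points are the 10 genes with the largest rise and the largest fall, and Hjurp lies at 79.7% in WT and 75.7% in cKO.

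The deleted gene and its paralogue were both marked. H2az1 (chromosome 3, 137864487 to 137866922) carried 1 WT peak, annotated TTS, which covered 7.80% of its 2436 bp. In cKO it carried 2 peaks covering 21.1%, 1 annotated TTS and 1 annotated promoter. The promoter-annotated peak (137866821 to 137867315) crossed the end of the gene span and lay mostly outside it. Its class may therefore belong to another gene, and it does not show a peak at the H2az1 promoter. The difference of 13.3 points depended on the peaks used. It was 29.0 points when peaks within 3 kb were joined. With a -log10 q of at least 5 or a fold enrichment of at least 4 it was -3.61 points, as the promoter-annotated peak alone remained in cKO. When the cKO list was reduced to the WT number of peaks or covered length, it was -7.80 points, as no cKO peak was left in the gene. The extent of the deleted segment is not given in the sources used here, so the peaks do not check the genotype. H2az2, the paralogous gene (chromosome 11, 6427226 to 6444511), had 9 WT peaks covering 16.2% and 8 broader cKO peaks covering 54.3% (1.71 points with joined peaks and -4.75 at matched covered length). The Nkx2 family, homeobox regulators of ventral brain and other organs, had no peak in the body of any of its 7 genes in either genotype. The 1 peak within 10 kb of any of them was a cKO peak near Nkx2-4 (chromosome 2, 147074986 to 147075297), annotated to an intron.

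Genes of the machinery that handles H2A.Z and H3K36 methylation were widely marked, and the median coverage of both lists was higher in cKO. Of 24 genes of the H2A.Z exchange and chaperone complexes, 21 were marked in WT and 22 in cKO, and 20 of the 23 members of at least 5 kb were higher in cKO by the rule. As in all lists, shorter members could not be called. Ruvbl1, an ATPase shared by the exchange complexes, went from 4.25 to 63.3%. Trrap, the scaffold of the TIP60-p400 complex, went from 25.9 to 81.9%, and Yeats4, an acetyl-lysine reader, from 10.8 to 62.4%. Of 28 genes for H3K36 methyltransferases, demethylases and readers, 22 were marked in WT and all 28 in cKO, and 18 of 27 were higher. Glyr1, whose product binds H3K36me3 nucleosomes, went from 16.6 to 76.0%, Brpf1 from 21.1 to 70.7% and Phf1 from 4.58 to 52.8%. The list medians differed by 35.4 and 23.6 points, inside the central 95% of 10000 random lists matched on coverage and gene length (25.5 to 40.2 and 20.2 to 29.2). The matched coverage includes that of cKO, so lying inside does not show that these lists behave like other genes. At matched covered length the median of the exchange list was -0.447 points, outside its matched lists (-0.242 to 5.37, percentile 1.1). That of the H3K36 list was 0, inside its range (-0.192 to 0.673). Glyr1, Brpf1 and Phf1 then had -2.68, -4.77 and -4.58 points, with no cKO peak left in Phf1.

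Setd2 itself, the main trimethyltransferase of H3K36, was chosen for display after its values were seen. The gene (chromosome 9, 110532500 to 110618633) carried 9 WT peaks over 5.03% of its 86134 bp and 45 cKO peaks over 32.2%. The WT peaks were scattered over the gene, and each of them was overlapped by a cKO peak. At matched covered length the difference was 0.0163 points.

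**Figure D3:**
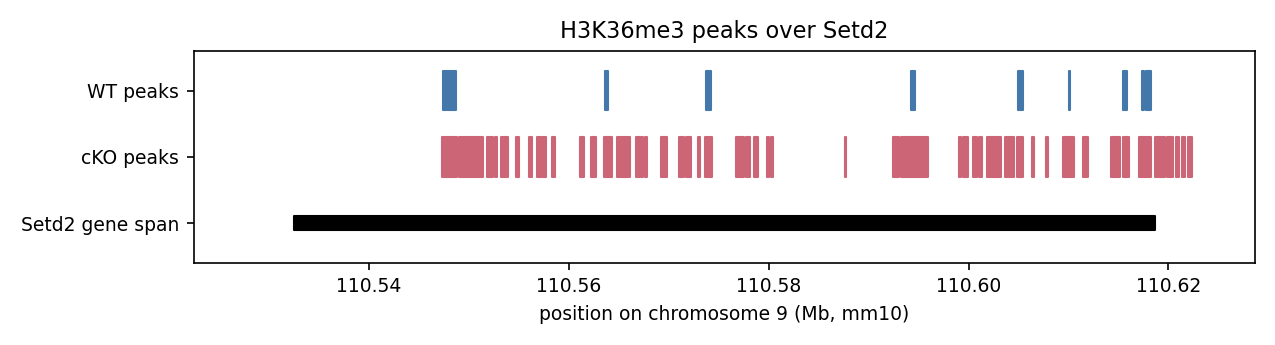
Positions of WT peaks (blue) and cKO peaks (red) along chromosome 9 (Mb, mm10) over Setd2, with the gene span in black. The 45 cKO peaks in the gene cover 32.2% of it and the 9 WT peaks 5.03%.

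Genes of radial glia and neural progenitors, the labelled cell type, were mostly marked in both genotypes. Of 33 such genes, 28 were marked in WT and 30 in cKO, and 16 of the 24 long enough to be called were higher in cKO. The largest differences in the list were those of Ccnd1 (cyclin D1) from 4.72 to 61.1%, Top2a (topoisomerase II) from 29.4 to 85.6% and Cdk1 from 29.0 to 76.9%. With joined peaks Top2a and Cdk1 differed by 2.96 and 6.75 points, and at matched covered length Ccnd1, left without a cKO peak, had -4.72. The median difference of the list was 14.8 points, under the 18.3 to 29.0 points of the matched random lists (percentile 0.04). Matching on the mean coverage of both libraries did not equalise WT coverage. A gene covered in WT has less room to gain, so the low percentiles of this list and the next may reflect that limit. Against random lists that were not matched the median of the radial glia list lay above their range of 0 to 4.86 points. Of the 21887 genes drawn from, 12213 had no peak in either genotype, so any list of mostly marked genes would lie above such lists. At matched covered length the median was -0.261, inside the -1.58 to 0 of its matched lists. Ubiquitously transcribed genes stood apart from their matched lists in the same direction. Of 40, 36 were marked in WT and all 40 in cKO, 23 of 26 were higher, and the median difference was 22.0 points against 27.0 to 39.1 (percentile 0.05), but above the 0 to 3.92 points of unmatched lists. At matched covered length this list, too, lay inside its range (0.909 against 0.773 to 12.8). Gpi1, a glycolytic enzyme, went from 16.2 to 79.1%, Npm1 (nucleophosmin) from 12.3 to 62.0% and Tbp, the TATA-binding protein, from 8.88 to 57.3%. At matched covered length these became 0.955, -12.3 and 5.02 points. Going against the list, Tubb5 (tubulin) had 70.8% in WT and 65.7% in cKO, and Eef2, the translocation factor of translation, had 72.2 and 69.6%, with a difference of -72.2 points at matched covered length and 3.18 with joined peaks. Tubb5 differed by 0.434 points with joined peaks. At matched covered length Npm1 and Eef2 had no cKO peak left, so their values are their WT coverage with a minus sign.

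Genes of intermediate progenitors and neurons mostly had low coverage in both genotypes. Of 14 genes of intermediate progenitors, 7 were marked in WT and 6 in cKO, and 2 of the 7 of at least 5 kb were higher. Btg2, an antiproliferative gene of neurogenic divisions and under 5 kb long, had 19.3 and 51.9%. Mfng, a modifier of Notch, went from 9.63 to 37.4%. Gadd45g (chromosome 13, 51846675 to 51848475) had 28.9% of its 1801 bp covered in WT and no cKO peak, a difference of -28.9 points in a gene too short for the rule. Of 30 genes of cortical excitatory neurons, 10 were marked in WT and 14 in cKO, and 1 of 27 was higher. That gene was Tubb3, the neuronal tubulin, with 27.6% in WT and 38.7% in cKO. Nfib (0.678 and 4.03%) and Map2 (0.454 and 3.15%) had smaller values, while Fezf2, which specifies deep-layer projection neurons, had 2.33% in WT and no cKO peak, and Reln had 0.0530% in WT and none in cKO. Of 24 genes of the ganglionic eminences and inhibitory neurons, 6 were marked in WT and 5 in cKO, and 1 of 15, Sp8, was higher with 0 and 11.95%. Dlx2 had 14.5 and 6.33%, and Sp9 (4.32%) and Gad2 (0.722%), which encodes a GABA-synthesising enzyme, were marked in WT alone. The median difference of each of the 3 lists was 0 points, inside the matched random lists (0 to 0.820, 0 to 0.269 and 0 to 0). Of the members, 7 of 14, 14 of 30 and 17 of 24 had no peak in either genotype. Their matched genes had none either, which held the random medians near 0, so no conclusion is drawn from these ranges. The mean coverage of intermediate progenitor genes was 8.12% in WT and 13.2% in cKO. The mean difference of that list was 2.42 points with joined peaks, -0.345 at matched number and -3.87 at matched covered length. With joined peaks Btg2 and Tubb3 differed by 2.94 and 1.22 points. Btg2, Mfng and Tubb3 turned to -19.3, -9.63 and -6.70 points at matched covered length, where Sp8 had 0. Btg2 and Mfng then had no cKO peak left.

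Genes of other cell types that a forebrain sample could hold were largely unmarked in both genotypes. Of 16 genes of the astrocyte and oligodendrocyte lineage, 1 was marked in WT and 3 in cKO. The gap junction gene Gja1 was higher, with 3.19 and 17.0%, and the myelin gene Mbp (0.474%) and Pdgfra (0.414%) had cKO peaks alone. In microglia and macrophages 0 of 14 genes were marked in WT and 1 in cKO, Csf1r with 7.02%. In endothelium and pericytes 0 of 14 were marked in either. Of 14 erythroid genes, 0 were marked in WT and 2 in cKO, Epb42 (1.13%) and Alas2 (1.00%). Among the unmarked ones, the reference places Hbb-b1 on chromosome 7 at 38285 to 39684, far from Hbb-bs at 103826523 to 103827928. This may not be a position on the mm10 chromosome, so its lack of a peak is not informative. Of 14 genes of meninges and fibroblasts, 0 were marked in WT and 2 in cKO, Zic1 (10.7%, higher by the rule) and Prrx1 (1.41%). Patterning genes of the diencephalon, midbrain and other regions had 0 of 23 marked in WT and 2 in cKO, Tcf7l2 (2.28%) and Lhx9 (1.52%). Genes of other organs not used in brain had 0 of 40 marked in WT and 3 in cKO, the surfactant gene Sftpb (10.2%, higher by the rule), Lct (1.05%) and Amh (0.0410%). The calls of Zic1 and Sftpb were lost when the cKO list was reduced to the WT number of peaks (3.16 and 0 points) or covered length (0 for both).

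The last groups were p53 targets and long adhesion genes. Of 22 genes of the DNA damage response and p53 targets, 10 were marked in WT and 14 in cKO, and 8 of 19 were higher. Mdm2, the ubiquitin ligase of p53, went from 27.9 to 72.4%, the apoptosis gene Bax from 8.85 to 41.0%, and the kinase gene Plk2 from 0 to 26.5%. The median difference of 3.73 points lay inside the 2.99 to 6.15 points of the matched lists. At matched covered length Bax, left without a cKO peak, had -8.85 points. Mdm2 differed by 9.505 points with joined peaks, and Plk2 by 0 at matched number. For the list, joined peaks gave 11 higher genes and a median of 10.7 points, matched number 3 and 0, and matched covered length 1 higher and 1 lower gene. Of 24 genes of the protocadherin clusters and long synaptic adhesion genes, 5 were marked in WT and 10 in cKO, and 0 were higher. Pcdhgc3 (4.74 and 12.8%) and Pcdhga1 (2.84 and 7.54%) share the end of the gamma cluster on chromosome 18, so their spans hold some of the same peaks. With peaks within 3 kb joined these were higher, by 31.1 and 15.1 points. Cntnap2, which spans 2241333 bp, had 0.0695 and 0.281%, and Cdh12 had 0.0346 and 0.0216%. With the full lists, no member of at least 5 kb in any of the 18 lists was lower by the rule. Members with under 10% coverage in WT could not be.

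**Figure D4:**
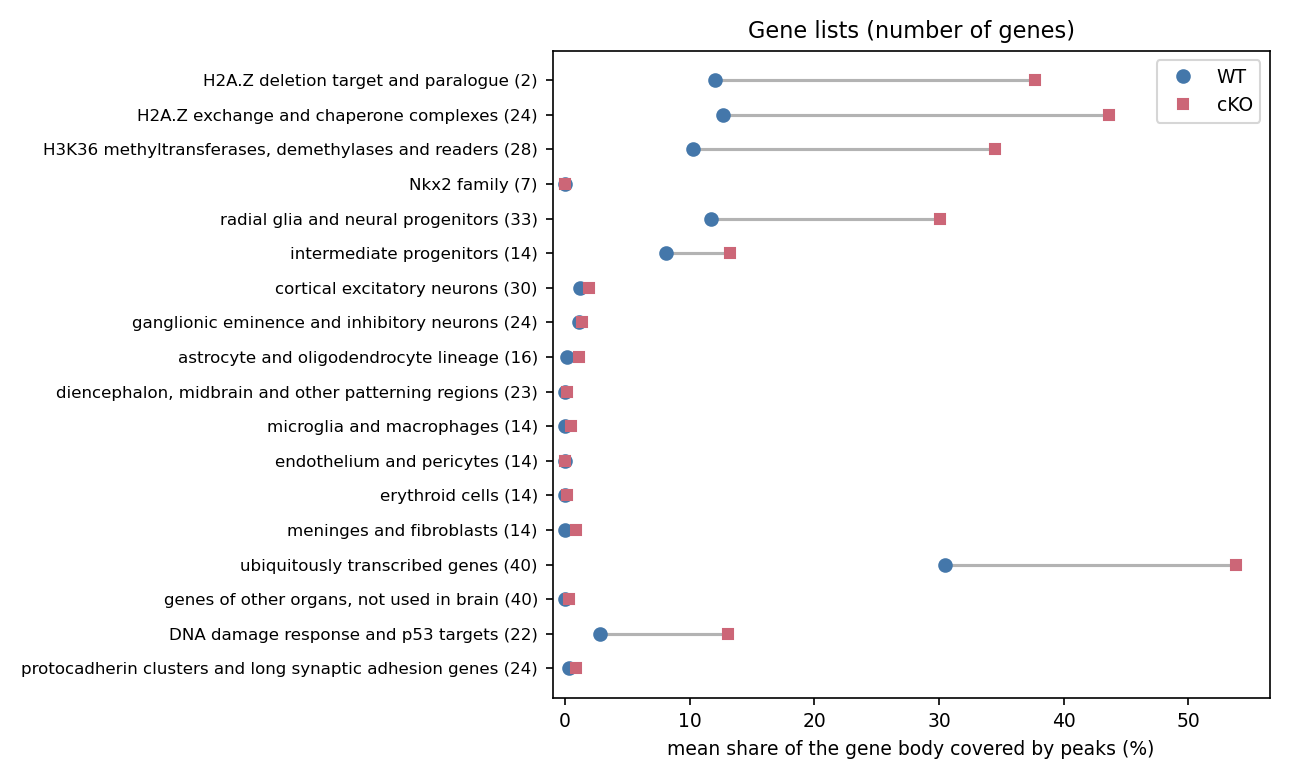
Mean share of the gene body covered by peaks (percent) in WT (blue circles) and cKO (red squares) for each of the 18 gene lists, with the number of genes in brackets; 1 library per genotype, so no error bar is drawn. Ubiquitously transcribed genes had means of 30.5% and 53.8%, cortical excitatory neuron genes 1.18% and 1.93%, and genes of other organs 0 and 0.283%.

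The strongest single peaks differed in kind between the libraries. Peak scores here are the authors' values and order peaks within 1 list. The 5 strongest WT peaks included a pair near the start of chromosome 10 (3111152 to 3117250 and 3109335 to 3110507), both intergenic, with a -log10 q of 257 and 214 and no cKO partner. They also included a pair in an intron of Tusc3 on chromosome 8 (39155186 to 39156085 and 39152741 to 39153512), both shared with cKO, and an intergenic peak on chromosome Y (11857983 to 11858500) without a cKO partner. All 5 strongest cKO peaks were shared with WT. They were annotated to the TTS of Dpm1 (chromosome 2, 168219201 to 168220273), an intron of Chd4 (chromosome 6, 125104147 to 125112220), an intron of Nupl2 (chromosome 5, 24136054 to 24137519), the TTS of Zfp146 (chromosome 7, 30160681 to 30163686) and an intron of Acap3 (chromosome 4, 155896974 to 155900579). Of the 10 strongest WT peaks without a cKO partner, 8 were intergenic and 3 lay on chromosome Y. Of the 10 strongest cKO peaks without a WT partner, 1 was intergenic and 7 lay on chromosome 8, of which 6 fell between 20144355 and 20583757. The other 3 were annotated to an intron of the predicted gene Gm16206 (chromosome 3, 53455890 to 53457656), an intron of Cage1 (chromosome 13, 38056939 to 38058521) and an exon of Ddx27 (chromosome 2, 167030391 to 167032489). The local background of several of these peaks was high, with a median of 3.92 times the genome background over the 10 cKO peaks and 1.03 times over the 10 WT peaks.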

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

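The comparison with the authors' gene names was chosen after seeing the data, and the other alternatives before. With 1 library per genotype no replicate could be left out. No paired analysis was possible because each genotype had 1 ChIP library and no test was made. The number of peaks, the genes marked in both, and the count of genes higher in cKO stayed within 1.5 times of their values under both stricter thresholds, and the cKO list stayed the longer one under both. Among the values of single genes, lists and annotation classes under an alternative, 334 kept their call (some of these, all under 10 points, changed sign). Another 95 were 0 throughout and could hardly change. Of the rest, 22 that had differed by at least 10 points changed sign and 22 others moved. A further 12 newly reached 10 points and 20 fell short of it with the same sign or at 0. Genes under 5 kb are counted here, although the rule leaves them out. Of the 35 named genes higher by at least 10 points in the full lists, 13 were still higher by at least 10 points at matched covered length, 27 at matched number and 29 with joined peaks. At these depths a gene without a peak is not shown to lack the mark.

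A -log10 q of at least 5 left 21.1% of cKO peaks shared, 48.3% of WT and 61.8% of cKO peaks in introns, and 1 gene, Eef2, lower in cKO, and the difference of H2az1 became -3.61 points. A fold enrichment of at least 4 gave 26.2% of cKO and 91.9% of WT peaks shared, 61.4% of cKO peaks in introns, 1 lower gene (Tmem205) and again -3.61 points for H2az1. Joining peaks within 3 kb gave 13659 WT and 18617 cKO domains, of which 94.1% and 43.5% were shared, and 6 lower genes. It also took H2az2 (1.71 points), Top2a (2.96), Cdk1 (6.75), Btg2 (2.94), Tubb3 (1.22) and Mdm2 (9.505) under 10 points, and took Asmt (-14.4), Pcdhgc3 (31.1) and Pcdhga1 (15.1) past it. Covering at least 50% of a peak gave 94.9% of WT and 7.53% of cKO peaks, and a reciprocal 50% gave 15.5% and 5.95%. Requiring 2 peaks gave 244 genes marked in WT alone. Requiring 10% of the body gave 1909 genes marked in both, 5 in WT alone and 4567 in cKO alone. With the authors' gene names 352 genes were marked in WT alone. Without a minimum gene length 3 genes were lower (Gadd45g and Rpl34-ps1 among them). Against unmatched random lists 4 gene lists lay outside the central 95%, where 2 had with matching.

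Reducing the cKO list to the WT number of peaks, from the strongest down, gave 81.1% of WT and 51.5% of cKO peaks shared, 56.8% of cKO peaks in introns, 527 genes marked in WT alone and 1169 in cKO alone, and 3730 higher and 5 lower genes, Tmem205 and Eef2 among the latter. Phf1, Mfng and H2az1 then had -4.58, -7.01 and -7.80 points. The counts of higher genes were 10 in radial glia and 3 among p53 targets, and the medians of the exchange, H3K36 and radial glia lists were 20.9, 12.9 and 5.80 points.

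Reducing the cKO list to the WT covered length changed the most results. It left 5308 cKO peaks with a median width of 1928 bp, so by construction few genes held any. Shared peaks were 30.7% of WT and 92.6% of cKO, and 48.9% of cKO peaks were in introns. Marked genes were 2977 in both, 3884 in WT alone and 54 in cKO alone, with 810 genes higher and 373 lower. The radial glia and ubiquitous lists then lay inside their matched random lists, and 1 other list, the exchange complexes, lay outside. Higher and lower genes numbered 6 and 2 in the exchange complexes, 2 and 1 in the H3K36 list, 5 and 5 in radial glia, and 6 and 5 among ubiquitous genes. Tmem205 (-12.8), Hjurp (-15.8), Dlx2 (-14.5) and Eef2 (-72.2) passed 10 points downward. The median differences of the deletion target with its paralogue, the exchange complexes and radial glia turned to -6.27, -0.447 and -0.261 points. The named genes that turned from a difference of at least 10 points were Npm1 (-12.3 points), Btg2 (-19.3), Glyr1 (-2.68), Clptm1l (-3.91), Phf1 (-4.58), Ccnd1 (-4.72), H2az2 (-4.75), Brpf1 (-4.77), Pla2g4b (-5.44), Ogfr (-6.61), Tubb3 (-6.70), H2az1 (-7.80), Bax (-8.85) and Mfng (-9.63). Of these, only Glyr1, H2az2, Brpf1 and Tubb3 kept a cKO peak. The others, like Tmem205, Dlx2 and Eef2, had none left, so their values are their WT coverage with a minus sign. The causes of the other changes were not tested.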

Other observations

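The gene families and single genes in this paragraph and the next were chosen after seeing the data. Most members of several families of widely transcribed genes carried the mark in both genotypes, and the median or mean coverage of each family was higher in cKO. Splicing factor genes (Srsf and Sf3) were marked in 18 of 20 cases in both, with a median coverage of 17.7% in WT and 51.8% in cKO. The Mcm and Orc genes of DNA replication were marked in 15 of 16 cases in WT and 16 in cKO, with medians of 6.63% and 53.1%. Ribosomal protein genes (Rpl and Rps) were marked in 61 of 77 cases in WT and 68 in cKO, with medians of 27.8% and 52.7%. Zinc finger genes (Zfp) were marked in 254 of 397 cases in WT and 328 in cKO, with mean coverage of 5.88% and 21.3%. Families that are silent in brain stayed nearly free of peaks. None of 1110 olfactory receptor genes and none of 56 keratin-associated genes had a peak in either genotype, and 0 of 355 vomeronasal receptor genes had one in WT and 2 in cKO. Potassium channel genes, which neurons use as they mature, were marked in 3 of 94 cases in WT and 12 in cKO, and collagen genes in 1 and 4 of 44.

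Within the radial glia list the differences ranged widely. Coverage of the proliferation gene Mki67 was 31.7% in WT and 72.3% in cKO, and that of Pcna 16.1% and 49.8%. Dbi (7.80 and 44.6%), the intermediate filament gene Vim (23.2 and 55.1%), the Notch effector Hes5 (13.7 and 42.8%) and the homeobox gene Emx2 (4.42 and 33.4%) differed by similar amounts. Sox2 (19.4 and 25.2%) and Nes (26.6 and 31.4%) differed less, Hes1 had no WT peak and 9.80% in cKO, and Fabp7, Hopx and Sox3 had no peak in either. X-linked genes were marked in 61 of 966 cases in WT and 213 in cKO, so that 26.8% of those marked in cKO were also marked in WT, against 71.6% on the autosomes. By length, the marked genes of 5 to 20 kb had median coverage of 8.66% in WT and 44.9% in cKO, and those over 100 kb 0.522% and 4.61%.

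All tests in the next 3 paragraphs were chosen after the results were seen. The first pattern is the wider cKO coverage. Sequencing depth does not account for it, since the cKO ChIP library held 1.03 times the WT tags while the covered length was 5.18 times as large. A spread of called peaks into untranscribed genes is argued against by the genes of other organs. Their mean coverage differed by 0.283 points, beside 23.4 points in ubiquitously transcribed genes. Signal below the calling threshold would not show in this measure, so a weaker spread is not excluded. Outside genes, intergenic peaks numbered 814 of 36820 in WT and 2830 of 95750 in cKO. The longer modelled fragment in cKO (185 against 152 bp), better enrichment in the cKO immunoprecipitation and a true gain of H3K36me3 may each widen peaks over genes that already carry the mark, and with 1 library per genotype and no spike-in all 3 stay open and untested.

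The second pattern is in genes of intermediate progenitors, cortical neurons and inhibitory neurons, 3 lists put together after their values were seen, where 5 of the 23 genes marked in WT (21.7%) had no cKO peak, namely Gadd45g, Fezf2, Gad2, Sp9 and Reln, against 106 of all 6861 WT-marked genes (1.54%). In the other direction, 7 of the 45 without a WT peak (15.6%) had a cKO peak, against 2813 of all 15026 such genes (18.7%). Each of the 5 had 1 WT peak, and of all genes with 1 WT peak 92 of 1776 (5.18%) were lost, against 5 of 9 in these lists. To allow for the choice of lists, the 148 WT-marked members of all 18 lists were replaced 10000 times by genes matched on covered WT bases and gene length. In 0.2% of the draws the 3 lists with the most losses lost as many. This argues against a small covered length in WT as the whole cause. The draws were not matched on peak strength or number of peaks, so weak peaks in WT stay open as a cause. The losses were 4 of 20, 6 of 22 and 8 of 23 genes under the q threshold, the fold threshold and the matched number of peaks, where 1.32, 2.33 and 7.68% of all WT-marked genes were lost, and fewer neurons in the cKO sample, lower transcription of these genes in each cell, and a bias from GC content may each give such values and stay open.

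The third pattern is the strong peaks found in 1 library alone. In cKO, 6 of the 10 strongest lay between 20144355 and 20583757 on chromosome 8, a stretch with 48 cKO and 13 WT peaks. The median local background of these 48 peaks was 5.48 times the genome background, against 1.06 over all cKO peaks and 2.59 over the 10 strongest cKO peaks with a WT partner, which is consistent with extra copies or reads shared between near-identical copies that also enter the input, although a raised background was not confined to peaks without a partner. For the 10 WT peaks the median was 1.03 times, with 4 of 10 at 2 times or more, which argues against such copies as a common explanation of the 10. Copies carried by the ChIP animals alone stay open and were not tested, and chromosome Y, which held 3 of the 10, had 18 WT and 77 cKO peaks in all.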
